A study of Mus musculus with 9 samples.

How the data were processed

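RNA of cultured mouse podocytes was measured on 9 single-colour arrays in 3 groups of 3. The deposited values are log2 values, 1 per probe set and array, made by the authors with affy and RMA, per the submitters' processing notes. RMA corrects the background, makes the probe distributions of the arrays alike and summarises the probes of a set by median polish. Versions, array annotation and genome build are not given in the sources used here. Because the distributions were made alike before deposit, a change in the total amount of RNA per cell cannot be seen, and changes are relative to the bulk of the genes. The scanner files were not used here, so background and detection of single probe sets were not checked. The number of arrays limits the precision.

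The value table holds 41345 probe sets. The annotation given pairs 23521 of them with 1 gene symbol, 1814 with several and 16010 with none. Symbols were checked through Entrez IDs in a RefSeq gene table of assembly GRCm38.p6, used for names alone; 23328 of the probe sets with 1 symbol matched and 0 symbols changed. For each gene the probe set with the highest mean over all 9 arrays was used, which gave 22180 genes, and probe sets with several or no symbols were left out. Of 1082 genes with more than 1 probe set, 10, 0 and 10 had probe sets called in opposite directions in the 3 comparisons. Ties were checked: each of the 36 pairs of arrays shared between 1022 and 1946 exactly equal values, with no pair apart, and 5 probe sets, 3 of them tested genes, had 1 value on all 9 arrays. No control probe sets for 3' to 5' ratios were identified, so RNA quality was not checked that way.

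Groups and replicate numbers were taken from the sample titles. All 9 arrays entered 1 limma fit of group means (limma 3.58.1 in R 4.3.3) with 6 residual degrees of freedom and no covariate, and 3 two-sided contrasts were tested with eBayes. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested, and counted again with an absolute log2 change of at least 1. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 29 lists in each comparison. Of 679 list members fixed, 622 were measured and 57 were not, 20 of these because they lie only on probe sets with several symbols. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

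The genes named were set by a rule. Per comparison it takes the 10 largest rises and the 10 largest falls among called genes whose higher group mean lay above the median of all probe sets, 5.83, and whose groups did not overlap, passing over clone and predicted names. It adds a fixed set of single genes, and from each list up to 4 called members with the largest change, or the 2 with the highest mean where none was called. Genes named outside the rule are marked as such. Design, lists, rule and the first set of alternatives below were fixed before the data were examined.

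The procedure was tested on simulated data with the mean DMSO values and the real within-group variances of 22180 genes. Noise was drawn independently for each gene, and 200 genes were changed in each of 5 draws per comparison. The real comparisons called 7768, 1745 and 7662 genes. The share recovered depends on how many genes change, so the shares below are not those of the real comparisons. For thapsigargin against DMSO, 4.8%, 69.2%, 98% and 100% of genes changed by 0.25, 0.5, 1 and 2 on the log2 scale were recovered, and 5.16% of the calls were false. For thapsigargin with forskolin against thapsigargin the shares were 8%, 67.2%, 96.8% and 100%, with 3.27% false, and for thapsigargin with forskolin against DMSO 7.6%, 72%, 98.8% and 99.6%, with 5.44% false.

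The alternatives fixed beforehand were a fit of the 6 arrays compared, eBayes with an intensity trend and robust prior, array weights, centring on array medians, another quantile normalization, a filter on dim genes, all probe sets or their mean per gene, limma's treat at 0.5, the replicate number as a block, and each array left out in turn. For the lists, an estimated correlation and fry were run. Alternatives chosen after seeing the data were the first component of the within-group deviations as a covariate, DMSO replicate 1 and combined replicate 1 left out together, the array of each group farthest out on that component left out, and, for the lists, another quantile normalization.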

Results

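Gene expression was measured on 9 single-colour arrays of cultured mouse podocytes, the epithelial cells that cover the capillaries of the kidney glomerulus. The cells had been differentiated for 11 days at 37 °C. 3 arrays came from cells given the vehicle DMSO, 3 from cells given 2.5 µM thapsigargin for 16 hours, and 3 from cells given 2.5 µM thapsigargin together with 10 µM forskolin for 16 hours. Thapsigargin blocks the SERCA pump that fills the calcium store of the endoplasmic reticulum (ER), and forskolin activates adenylyl cyclase, which makes cAMP. The labels call the 3 arrays of a group biological replicates but do not say in what they were separate, so the p-values measure the spread between these arrays, which limits what they cover. A value is given per gene for 22180 genes, and errors of changes are limma standard errors with 3 arrays per group. No coordinates are given, because no genome build is named in the sources used here.

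The arrays of a group were alike. Pearson correlations over all 41345 probe sets lay between 0.989 and 0.993 within groups and between 0.966 and 0.992 between groups. The first principal component held 72.8% of the variance over the tested genes and separated DMSO from both thapsigargin groups, and the second held 9.83% and separated thapsigargin alone from thapsigargin with forskolin. The median log2 value of an array lay between 5.80 and 5.88. It was lower on the thapsigargin arrays than on the DMSO arrays and than on the combined arrays, each with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 arrays can give.

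**Figure D1:**
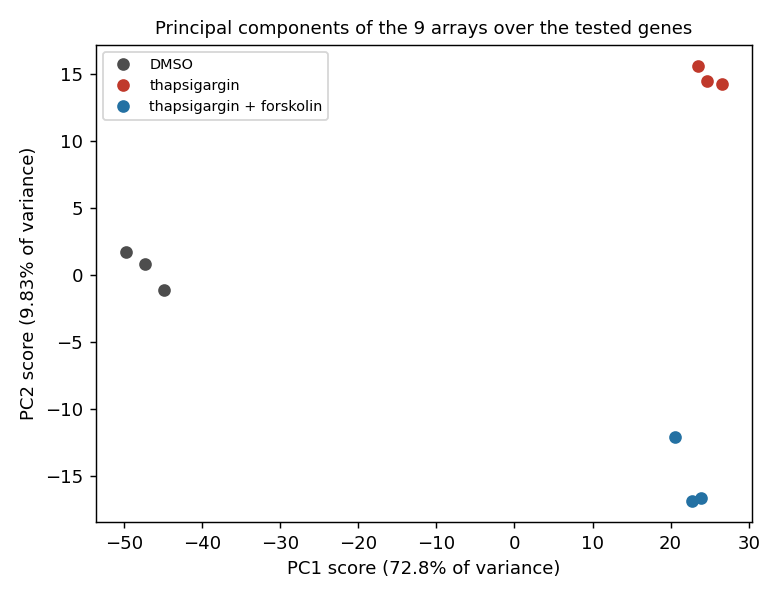
Scores of the 9 arrays on the first component (72.8% of the variance, horizontal axis) and the second component (9.83%, vertical axis), computed over the tested genes; each point is 1 array and colours mark the 3 groups. The DMSO arrays lie apart from the other arrays on the horizontal axis, and the 2 thapsigargin groups lie apart on the vertical axis.

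The first comparison asked which transcripts differed after thapsigargin. Genes of the ER stress response were among those raised most. Aldh1l2, a mitochondrial folate enzyme, rose 22.8-fold (log2 change 4.51 ± 0.11), the cystine transporter gene Slc7a11 rose from a mean log2 value of 4.74 to 9.07 and the pseudokinase gene Trib3 rose 14.3-fold (3.83 ± 0.09). Ddit3, which encodes the transcription factor CHOP, rose 6.72-fold (2.75 ± 0.06) and the ER chaperone gene Hspa5 rose 3.02-fold. In the other direction Inmt fell by 4.27 ± 0.09 on the log2 scale and Lbp, which encodes a lipopolysaccharide-binding protein, fell by 4.12 ± 0.06. In limma with Benjamini-Hochberg adjustment, 4026 genes were higher and 3742 lower, of which 684 and 653 changed at least 2-fold. The values of the 2 groups did not overlap for 43.9% of all genes, where chance gives 10%.

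The remaining genes among the 10 largest rises were Cdsn, Cth, Apobec1, Ero1b, Atf3, Sdf2l1 and Sprr1a, with log2 changes from 3.70 for Cdsn to 3.11 for Sprr1a. The other large falls were those of Hacd4, Pla1a, Iigp1, Ctxn3, Ms4a2, Plce1, C4bp and Spon2, from -3.88 for Hacd4 to -3.38 for Spon2. The genes that encode the sensors of ER stress and their factors rose too. The log2 change was 1.81 ± 0.06 for Atf6, 1.51 ± 0.07 for Ern1, 0.86 ± 0.05 for Eif2ak3, 1.16 ± 0.06 for Atf4 and 1.27 ± 0.05 for Xbp1. Atp2a2, which encodes the SERCA pump that thapsigargin blocks, rose by 1.77 ± 0.05. Txnip, which encodes a thioredoxin-binding protein, rose by only 0.23 ± 0.06 (limma adjusted p = 0.013), while its relative Arrdc4 rose by 1.48 ± 0.06.

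Of 29 gene lists fixed beforehand, 13 passed camera with its preset correlation, 6 upward and 7 downward, and 3 of the 13 also passed with an estimated correlation. These 3 were lists of the secretory pathway and its stress response. Of 24 measured ER chaperones and folding enzymes 22 rose and 0 fell, with Ero1b at 3.22, Sdf2l1 at 3.13, Creld2 at 2.97 and Dnajb9 at 2.71, and 22 and 0 adjusted over the list alone (camera adjusted p = 4.55e-18, and adjusted p = 0.024 with an estimated correlation). Of 25 PERK-ATF4-CHOP targets 23 rose and 1 fell, also adjusted over the list alone (adjusted p = 9.13e-18, and adjusted p = 0.00434 with an estimated correlation). The member that fell was Stc2, at -1.20, named after its value was seen. Of 30 genes of ER translocation and COPII export 25 rose and 1 fell, against 27 and 1 adjusted over the list alone, with Sec11c at 1.41 and Sec24d raised 3.04-fold (adjusted p = 5.96e-14, and adjusted p = 0.00434 with an estimated correlation).

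Other lists passed camera only with the preset correlation. Of 18 genes of ER-associated degradation 14 rose and 1 fell, with the same counts adjusted over the list alone, Herpud1 at 2.18 and Sel1l at 2.02 (adjusted p = 2.4e-08, and adjusted p = 0.0548 with an estimated correlation). Of 20 cytosolic ribosomal protein genes 17 rose and 0 fell, 18 and 0 adjusted over the list alone, by at most 0.61 for Rplp0 (adjusted p = 1.02e-06, and adjusted p = 0.154 with an estimated correlation). Of 19 genes of cholesterol synthesis and uptake 11 rose and 7 fell, also adjusted over the list alone, with Mvd at 1.54 and Cyp51 at 1.46 (adjusted p = 0.0454, and adjusted p = 0.41 with an estimated correlation). The call of the cholesterol list was also lost without DMSO replicate 1 (adjusted p = 0.0703), without thapsigargin replicate 3 (adjusted p = 0.0573), among genes above the median level (adjusted p = 0.22), after centring on the array medians (adjusted p = 0.0716) and after another quantile normalization (adjusted p = 0.102), the latter tried on lists after seeing the data. With the replicate number as a block the cholesterol list lost its call too (adjusted p = 0.0524).

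Matrix, cytoskeletal and lysosomal transcripts fell. Of 35 extracellular matrix genes 22 fell and 2 rose, also adjusted over the list alone, with the basement membrane genes Nid2 at -3.05 and Nid1 at -1.76 (adjusted p = 4.71e-07, and adjusted p = 0.0602 with an estimated correlation). The members that rose were Lox at 0.94 and Col5a1 at 0.57, named after their values were seen. Of 25 actin cytoskeleton genes and targets of the factor SRF 16 fell and 4 rose, 17 and 4 adjusted over the list alone, with the myosin light chain gene Myl9 at -1.68 and Tagln at -1.11 (adjusted p = 0.000188, and adjusted p = 0.114 with an estimated correlation). Of 25 genes of autophagy and the lysosome 17 fell and 4 rose, also adjusted over the list alone, with Hexa at -1.41 and Ctsa at -0.96 (adjusted p = 0.000188, and adjusted p = 0.076 with an estimated correlation). Of 18 YAP-TEAD targets 11 fell and 3 rose, 12 and 3 adjusted over the list alone, with Wwc1 at -1.21 (adjusted p = 0.00978, and adjusted p = 0.319 with an estimated correlation). Of 20 interferon-stimulated genes 11 fell and 2 rose, also adjusted over the list alone, with Irf1 at -1.43 and Ifit1 at -1.25 (adjusted p = 0.00519, and adjusted p = 0.37 with an estimated correlation).

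Podocyte genes fell more often than they rose, and so did markers of tubular cells. Of 35 measured podocyte genes 20 fell and 6 rose, also adjusted over the list alone (adjusted p = 0.00107, and adjusted p = 0.114 with an estimated correlation). Plce1, which encodes a phospholipase C, fell by 3.45 ± 0.08 and Synpo, which encodes the actin-binding protein synaptopodin, fell by 2.52 ± 0.08. Wt1 fell by 0.35 ± 0.08 and Podxl by 0.67 ± 0.11, while Nphs1, which encodes nephrin, differed by -0.16 ± 0.10 (limma adjusted p = 0.25). Of 15 tubular and other epithelial markers 5 fell and 0 rose, also adjusted over the list alone (adjusted p = 0.00757, and adjusted p = 0.154 with an estimated correlation), and the call was also lost among genes above the median level (adjusted p = 0.06). Cdh16 fell by 3.37 ± 0.05, and the water channel gene Aqp1 fell by 3.24 ± 0.05. The others were Cldn2, which fell to a mean of 3.97, below the lower quartiles of the arrays, Lrp2 at -1.03 and Krt19 at -0.22, the last named after its value was seen. The lists of mesangial and pericyte (adjusted p = 0.11), macrophage and leukocyte (adjusted p = 0.144) and endothelial markers (adjusted p = 0.75) did not pass, with single falls such as those of Pdgfrb at -1.23, Csf1r at -1.18 and Ehd3 at -1.21.

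The lists of pro-apoptotic, cAMP-CREB response and cell cycle genes did not pass. Among 22 pro-apoptotic genes 5 rose and 11 fell, 5 and 14 adjusted over the list alone (adjusted p = 0.11), with Casp4 raised 4.01-fold, Fas at -2.28 and Casp12 at -2.26, and this list passed downward after another quantile normalization (adjusted p = 0.0331). Among 24 cAMP-CREB response genes 8 rose and 8 fell, also adjusted over the list alone (adjusted p = 0.75), with Nfil3 at 2.27 and Fos at -2.51. Among 30 cell cycle genes 10 rose and 4 fell, 11 and 6 adjusted over the list alone (adjusted p = 0.106), with Cdc45 at 1.11, and this list passed upward without DMSO replicate 3 (adjusted p = 0.032). In 12 list results that did not pass, over the 3 comparisons, the median or the mean differed in sign from the test, as for the cAMP-CREB list here.

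**Figure D2:**
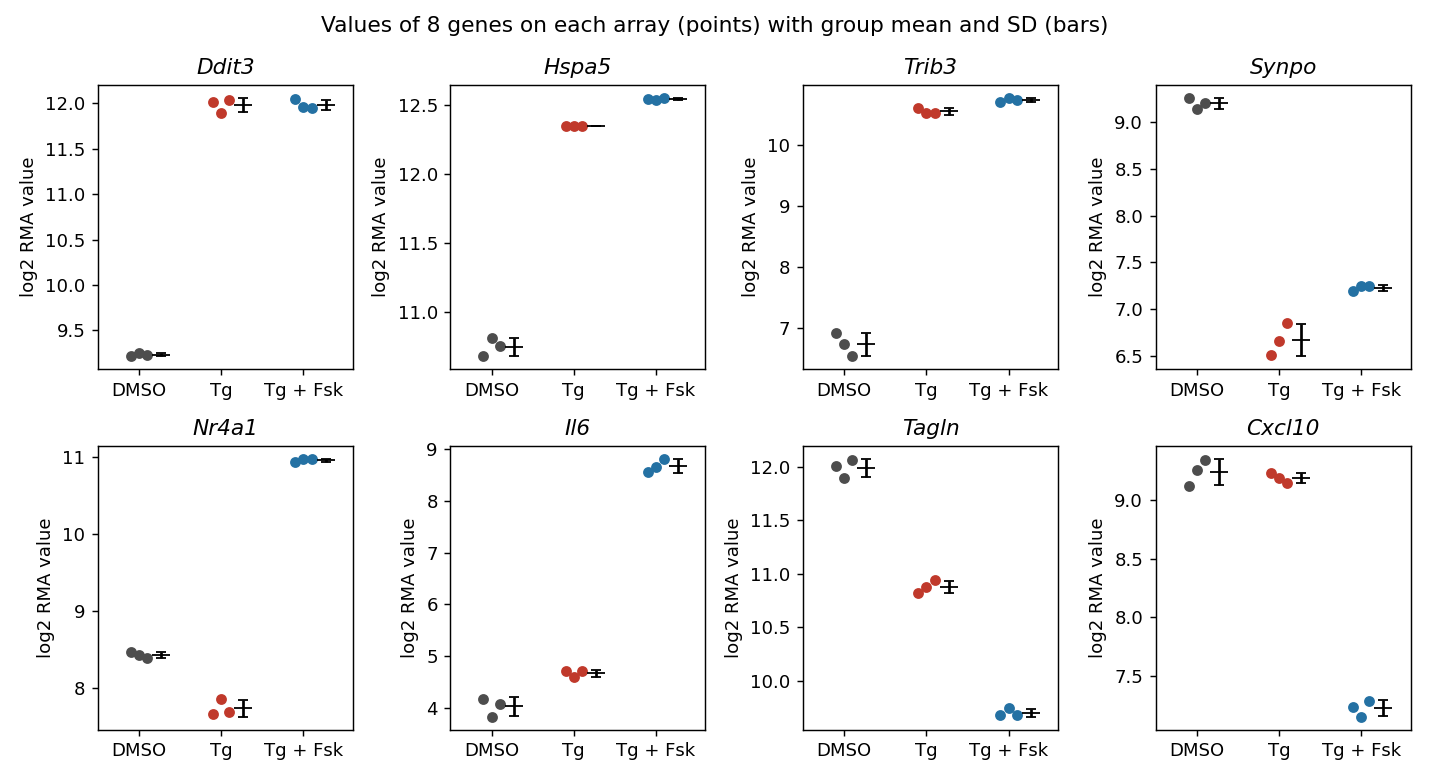
Log2 RMA values (vertical axes, which differ between panels and do not start at 0) of 8 genes in the DMSO, thapsigargin (Tg) and thapsigargin with forskolin (Tg + Fsk) groups; points are single arrays and bars beside them the mean and SD of 3 arrays. Ddit3, Hspa5 and Trib3 lie higher in both thapsigargin groups than in DMSO, Synpo and Tagln lie lower, and Nr4a1 and Il6 lie highest and Cxcl10 lowest in the combined group.

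The second comparison asked what forskolin added to thapsigargin, with thapsigargin alone as the reference. The nuclear receptor genes Nr4a1 and Nr4a3 rose 9.29-fold (3.22 ± 0.06) and 8.38-fold (3.07 ± 0.05), and Vdr, which encodes the vitamin D receptor, rose 7.24-fold (2.86 ± 0.05). Il6, which encodes an inflammatory cytokine, rose to log2 values between 8.56 and 8.82. Its values on the DMSO and thapsigargin arrays, between 3.83 and 4.71, lay below or close to the lower quartiles of those arrays, 4.53 to 4.54, and no size of change is given for it because background was not checked. The cytokine gene Tnfsf18 fell by 4.45 ± 0.17 on the log2 scale. Ccl17, Cxcl10 and Ccl2, which encode chemokines, fell too, with log2 changes of -2.02 ± 0.11, -1.95 ± 0.07 and -1.67 ± 0.19. In limma 821 genes were higher and 924 lower, of which 60 and 29 changed at least 2-fold, and the values of the groups did not overlap for 26.1% of all genes, where chance gives 10%. The count of lower genes was 586, 568 and 600 without thapsigargin replicate 1, thapsigargin replicate 3 and combined replicate 2, beside 600, 615 and 550 higher. It was 361, beside 527 higher, when the array of each group farthest out on an axis of within-group variation was left out, an alternative chosen after seeing the data. Centring on the array medians gave 642 higher and 1083 lower genes, and another quantile normalization 930 and 930. Which direction held more genes thus depended on the scaling and the arrays.

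The other large rises were those of Mcam, Plau, Rgs2, Kcnj16, Tcim and Fgf7, from 2.58 for Mcam to 2.19 for Fgf7. The other large falls were those of Lox, Cmah, Nes, Fxyd5, Tgfb2 and Gask1b, from -1.90 for Lox, which encodes a collagen crosslinking enzyme, to -1.30 for Gask1b. Most of the ER stress genes reported singly did not pass the test. The log2 difference was 0.00 ± 0.06 for Ddit3, -0.01 ± 0.06 for Atf4, -0.01 ± 0.05 for Xbp1, -0.07 ± 0.06 for Atf6, 0.19 ± 0.09 for Trib3 and 0.04 ± 0.07 for Atf3, with limma adjusted p from 0.292 for Trib3 to 0.999 for Ddit3. Hspa5 rose by 0.20 ± 0.05 (limma adjusted p = 0.043) and Eif2ak3 by 0.22 ± 0.05 (limma adjusted p = 0.037). Hspa5 had exactly the same value, 12.34, on the 3 thapsigargin arrays, which lowered its spread as estimated over all groups. Synpo rose by 0.55 ± 0.08, Podxl fell by 0.79 ± 0.11 and Txnip fell by 0.24 ± 0.06 (limma adjusted p = 0.039).

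Camera with the preset correlation passed 17 of the 29 lists, 8 upward and 9 downward, and 2 of them also passed with an estimated correlation. Of 24 cAMP-CREB response genes 12 rose and 2 fell, 13 and 4 adjusted over the list alone, with Rgs2 at 2.48 and Nr4a2 at 1.40 (adjusted p = 1.78e-09, and adjusted p = 0.0449 with an estimated correlation). The members that fell were Egr1 at -0.67 and Arid5a at -0.24, named after their values were seen. Of 25 actin cytoskeleton genes and SRF targets 15 fell and 0 rose, 19 and 1 adjusted over the list alone, with Tagln at -1.18 and the smooth muscle actin gene Acta2 at -1.16 (adjusted p = 9.06e-14, and adjusted p = 0.0449 with an estimated correlation).

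The remaining passing lists lost their call with an estimated correlation. Of 16 ERK feedback and output genes 8 fell and 1 rose, 8 and 3 adjusted over the list alone, with Emp1 at -1.07 and Ccnd1 at -0.78 (adjusted p = 0.0011, and adjusted p = 0.162 with an estimated correlation). Of 30 cell cycle genes 7 fell and 0 rose, 7 and 1 adjusted over the list alone, with the replication licensing gene Mcm3 at -0.70 (adjusted p = 0.0011, and adjusted p = 0.333 with an estimated correlation). Of 35 extracellular matrix genes 10 fell and 4 rose, 15 and 4 adjusted over the list alone, with Lox at -1.90, Nid1 at -1.04 and Nid2 at 0.84 (adjusted p = 0.00266, and adjusted p = 0.206 with an estimated correlation). Of 16 NRF2 antioxidant genes 8 rose and 2 fell, 9 and 3 adjusted over the list alone, with Gstm1 at 0.47 and Abcc1 at -0.57 (adjusted p = 0.00288, and adjusted p = 0.11 with an estimated correlation). Of 25 PERK-ATF4-CHOP targets 7 fell and 0 rose, 8 and 1 adjusted over the list alone, with Slc7a11 at -0.50 and Stc2 at -0.38 (adjusted p = 0.0039, and adjusted p = 0.162 with an estimated correlation). Of 18 YAP-TEAD targets 6 fell and 2 rose, 9 and 4 adjusted over the list alone, with Tgfb2 at -1.37 and Ccn2 at -0.63 (adjusted p = 0.0253, and adjusted p = 0.333 with an estimated correlation). The call of the YAP-TEAD list was also lost after another quantile normalization (adjusted p = 0.0671).

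In the other lists that passed, few members changed singly. Among the interferon-stimulated genes Cxcl10 and Ifit2 fell, also adjusted over the list alone (adjusted p = 0.0011, and adjusted p = 0.268 with an estimated correlation), and among the p53 targets 4 fell and 1 rose, 8 and 1 adjusted over the list alone, with Plk2 and Perp both at -0.56 (adjusted p = 0.0016, and adjusted p = 0.162 with an estimated correlation). Among the genes of autophagy and the lysosome 3 rose and 1 fell, 10 and 3 adjusted over the list alone, with Ulk1 at 0.46 and Ctsl at -0.26 (adjusted p = 0.0039, and adjusted p = 0.162 with an estimated correlation). Hsd17b7 at 0.67 and Srebf2 at 0.35 rose among the cholesterol genes, where 6 rose and 2 fell adjusted over the list alone (adjusted p = 0.00745, and adjusted p = 0.268 with an estimated correlation), and Os9 at 0.43 and Edem1 at 0.27 among those of ER-associated degradation, where 3 rose adjusted over the list alone (adjusted p = 0.0163, and adjusted p = 0.268 with an estimated correlation). Among the ER chaperones Ero1b at 0.36 and Hspa5 at 0.20 rose, also adjusted over the list alone (adjusted p = 0.0354, and adjusted p = 0.333 with an estimated correlation); this list's median was 0.03, and -0.0027 after centring on the array medians, where its call was lost (adjusted p = 0.11). No cytosolic ribosomal protein gene changed singly, and 0 did adjusted over the list alone (adjusted p = 0.022, and adjusted p = 0.357 with an estimated correlation), and this list lost its call after another quantile normalization (adjusted p = 0.0754).

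Few markers of other cell types changed singly. Mcam at 2.58 and Pdgfrb at 0.38 rose among 9 mesangial and pericyte markers (adjusted p = 0.0356, and adjusted p = 0.206 with an estimated correlation), and Cd14 at 0.87 and Csf1r at 0.82 among 12 macrophage and leukocyte markers, in both lists also adjusted over the list alone (adjusted p = 0.0465, and adjusted p = 0.268 with an estimated correlation). The call of the macrophage list was also lost after another quantile normalization (adjusted p = 0.0595) and with the replicate number as a block (adjusted p = 0.0572). Without combined replicate 1 the ER chaperone, ribosomal, YAP-TEAD, macrophage and mesangial lists lost their calls (adjusted p = 0.0848, 0.0988, 0.0634, 0.105 and 0.128). The chaperone and ribosomal lists also lost theirs without thapsigargin replicate 1 (0.0900 and 0.102), the YAP-TEAD, macrophage and mesangial lists without thapsigargin replicate 3 (0.0755, 0.0805 and 0.0810), the chaperone and macrophage lists without combined replicate 3 (both 0.0527), the macrophage and mesangial lists without DMSO replicate 1 (0.0651 and 0.0535) and the macrophage list without DMSO replicate 3 (0.0570). The tubular list did not pass (adjusted p = 0.274), and 1 of its 15 markers, Cdh16, rose by 0.54 ± 0.05. The endothelial list did not pass either (adjusted p = 0.169), and 1 of its 12 markers, Flt1, fell by 0.32 ± 0.05. Of the 35 podocyte genes 4 rose and 10 fell, 7 and 10 adjusted over the list alone (adjusted p = 0.134), with Nes at -1.43 and Plce1 at -1.29. Of 22 NF-kB inflammatory genes 2 rose and 5 fell, 3 and 7 adjusted over the list alone (adjusted p = 0.148), with Tnfaip3 at -0.61, and this list passed downward among genes above the median level (adjusted p = 0.0228). Among the same genes the ribosomal, ER chaperone, mesangial and YAP-TEAD lists lost their calls (adjusted p = 0.0600, 0.0556, 0.0591 and 0.0692).

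**Figure D3:**
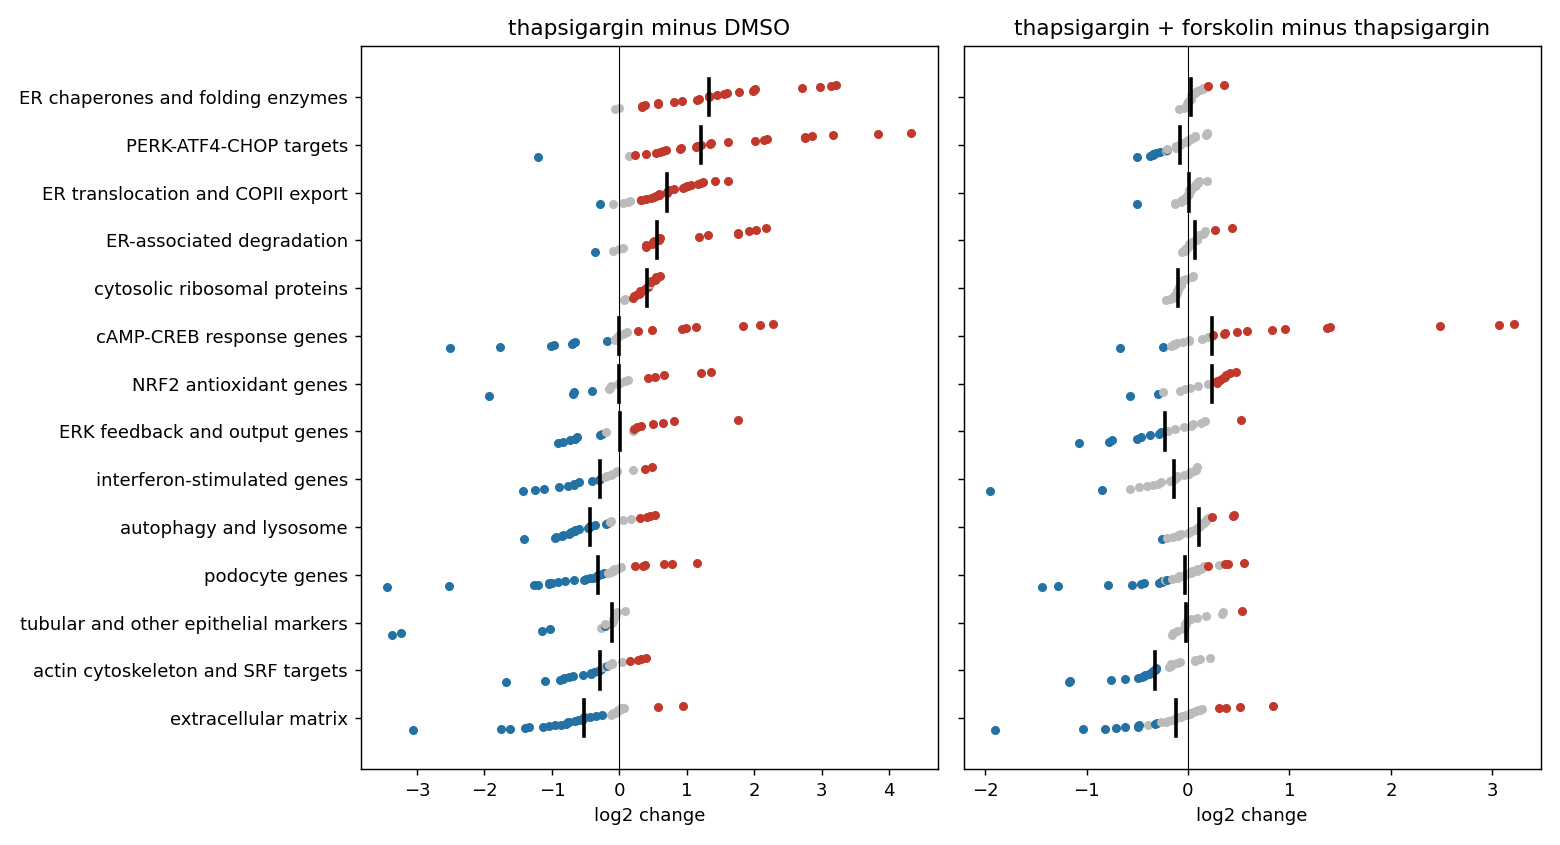
Log2 changes (horizontal axes, which differ between panels) of the measured members of 14 gene lists for thapsigargin minus DMSO (left) and for thapsigargin with forskolin minus thapsigargin (right); each point is 1 gene, red where it rose and blue where it fell at a limma adjusted p below 0.05, grey otherwise, and black bars are list medians. The ER lists lie to the right of 0 in the left panel and close to 0 in the right panel, and the actin list lies to the left of 0 in both.

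Genes that thapsigargin changed and that added forskolin also changed moved mostly the opposite way. Of the genes raised by thapsigargin, 524 fell and 132 rose further with forskolin. Of those lowered by thapsigargin, 542 rose and 262 fell further. Independent lists of these lengths would share 167.7, 149.0, 138.5 and 155.9 genes in the same order. Both comparisons use the 3 thapsigargin arrays, which alone pulls their changes in opposite directions, and 3 arrays cannot be split into parts of at least 2 each. The correlation of the log2 changes across genes, which are not independent replicates, was -0.276, against -0.0987 on average in 50 simulations with no effect of forskolin. The covariance was -0.0276, against -0.00498 on average and -0.00585 at the lowest in the simulations. Noise was simulated independently for each gene, so this range does not cover deviations shared by many genes. The 1066 genes that moved the opposite way were 675 without combined replicate 2 and 707 without combined replicate 3. The 394 that moved further were 255, 253 and 253 without thapsigargin replicate 1, 2 and 3. With the farthest array of each group left out, an alternative chosen after seeing the data, the counts were 496 and 198.

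The third comparison set thapsigargin with forskolin against DMSO. The ER stress genes were raised, with log2 changes of 4.02 ± 0.09 for Trib3, 2.75 ± 0.06 for Ddit3 and 1.80 ± 0.05 for Hspa5. Nr4a3 rose by 4.06 ± 0.05, Rgs2 by 3.41 ± 0.12 and Nr4a2 by 3.23 ± 0.05 on the log2 scale, and Il6 rose from values between 3.83 and 4.18, below the lower quartiles of the DMSO arrays. The largest falls included Ccl17 at -5.03 ± 0.11, Plce1 at -4.73 ± 0.08, Tnfsf18 at -3.88 ± 0.17 and Aqp1 at -3.40 ± 0.05. In limma 3963 genes were higher and 3699 lower, of which 571 and 599 changed at least 2-fold, and the values of the groups did not overlap for 42.6% of all genes, where chance gives 10%.

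The remaining large rises were those of Aldh1l2, Cdsn, Slc7a11, Ero1b and Atf3, and the remaining large falls those of Hacd4, Spon2, Col8a1, Iigp1, Sema7a and Cemip, the last at -3.25. Synpo fell by 1.97 ± 0.08 and Txnip differed by -0.01 ± 0.06 (limma adjusted p = 0.9). Camera passed 15 of 29 lists, 7 upward and 8 downward, and 6 also with an estimated correlation. Of these, ER chaperones rose in 22 of 24 members (adjusted p = 0.0176 with an estimated correlation), PERK-ATF4-CHOP targets in 22 of 25 (0.00504), ER translocation and COPII genes in 26 of 30 (0.00504) and genes of ER-associated degradation in 14 of 18 (0.0292). Extracellular matrix genes fell in 25 of 35 members (adjusted p = 0.0225 with an estimated correlation) and actin and SRF genes in 18 of 25 (0.0292), with Myl9 at -2.43, Tagln at -2.28 and Acta2 at -2.00. Adjusted over the list alone, these counts were 22, 22, 26, 14, 26 and 19. Over all genes tested, 1 member went the other way in each of these lists except the chaperones, and adjusted over the list alone 2 members of the translocation and COPII list did. Among the lists that passed with the preset correlation alone, cAMP-CREB response genes rose in 13 of 24 members and fell in 5 (adjusted p = 0.145 with an estimated correlation), cholesterol genes rose in 11 and fell in 5 (0.18) and ribosomal protein genes rose in 11 (0.163). Interferon-stimulated genes fell in 14 of 20 members and rose in 1 (adjusted p = 0.147 with an estimated correlation), YAP-TEAD targets fell in 12 of 18 and rose in 2 (0.147), genes of autophagy and the lysosome fell in 14 of 25 and rose in 4 (0.145) and pro-apoptotic genes fell in 14 of 22 and rose in 3 (0.163). Adjusted over the list alone, the larger counts were 13, 11, 11, 14, 12, 15 and 14. The podocyte list, in which 19 of 35 fell and 5 rose (22 and 5 adjusted over the list alone), passed with the preset correlation (adjusted p = 7.29e-05) and had an adjusted p = 0.0651 with an estimated correlation. The tubular list, in which Aqp1, Cdh16, Cldn2 and Lrp2 fell, had an adjusted p = 0.00521, and an adjusted p = 0.145 with an estimated correlation. Of 28 oxidative phosphorylation genes 12 fell and 2 rose, 13 and 2 adjusted over the list alone, and of 18 p53 targets 8 fell and 4 rose, 10 and 4 adjusted over the list alone. These lists did not pass (adjusted p = 0.0789 and 0.121) but did after another quantile normalization (adjusted p = 0.0112 and 0.0473), and the first also without DMSO replicate 1 (adjusted p = 0.0315). Of 22 NF-kB inflammatory genes 9 fell and 3 rose, also adjusted over the list alone (adjusted p = 0.0789), and this list passed among genes above the median level (adjusted p = 0.0195).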

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

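Except for the splits of the samples and the test of the array distributions, the tests in this part were chosen after the results were seen. The rule that a share must pass its bound by more than its jackknife error was also set after that share was known.

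Probe sets outside the tested genes carried signal that differed from the DMSO arrays. Among the 16010 probe sets without a symbol, limma called 1258 in thapsigargin against DMSO (838 higher, 420 lower), 1336 in thapsigargin with forskolin against DMSO and 11 in thapsigargin with forskolin against thapsigargin. Among the 1814 with several symbols it called 517, 490 and 98 in the same order. They are unnamed here. Outliers were not tested for, since each group has 3 arrays.

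For the number of genes called, each real split was set against the 9 others of the 10 splits of its 6 arrays into 3 and 3. It was 1 of 10 splits to call as many genes in each comparison. The real counts were 7768, 1745 and 7662 genes for thapsigargin against DMSO, thapsigargin with forskolin against thapsigargin, and thapsigargin with forskolin against DMSO, and the highest count of any other split was 0 each time. Each of the other splits mixes arrays of both groups, so any difference between the groups enters its spread and lowers its count. With 10 splits no share under 0.05 can be reached either, so these counts decide nothing.

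Genes changed by thapsigargin and also by added forskolin moved mostly the opposite way. They were a small part of the 7768 genes changed by thapsigargin, with 1066 moved the opposite way and 394 moved further. The covariance of the changes, -0.0276, lay below the lowest of 50 simulations with the shared thapsigargin arrays and no forskolin effect, -0.00585. This argues against chance values of those arrays that are independent between genes as the whole source. The simulations held no deviations shared by many genes, such as those along the axis described below. Such deviations of the thapsigargin arrays therefore stay open as a source. A weaker action of thapsigargin in the combined group stays open, since the ER stress lists differed: among members raised by thapsigargin, the 23 PERK-ATF4-CHOP targets kept a median of 91.2% to 93.2% of their change on the combined arrays, the 25 translocation and COPII genes 99.0% to 103.2%, the 22 chaperones 101.5% to 102.9% and the 14 genes of ER-associated degradation 107.9% to 109.7%. All 84 of these genes kept a median of 100.7% to 101.6%, the 1337 genes changed at least 2-fold 88.0% to 89.7%, and the 1066 that moved the opposite way, a share that decides nothing since they were picked for that movement, 51.7% to 52.7%. The 84 and the 1337 genes were picked by their change on the same thapsigargin arrays that the shares are measured against. This choice alone can lower the shares, by an amount that was not estimated. That forskolin acts against part of the thapsigargin response is a hypothesis, and no group with forskolin alone was analysed here to test it.

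More podocyte genes fell than rose under thapsigargin (20 and 6 of 35), and 5 of 15 tubular markers fell, although both lists lost their call with an estimated correlation (adjusted p = 0.114 and adjusted p = 0.154 with an estimated correlation). The median log2 change was -0.11 over the tubular list, and Cdh16 and Aqp1, at 11.16 and 11.71 in DMSO, fell most. A shift in share between these cell types was neither excluded nor shown, since podocyte genes went both ways and 10 tubular markers were not called.

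The arrays of a group varied along 1 axis that held 30.9% of the within-group variance, against 16.4% for the next. The scores of replicates 1, 2 and 3 on it were -14.6, 0.55 and 14.1 in DMSO, -0.427, -7.18 and 7.61 in thapsigargin, and -11.9, 2.91 and 9.01 in the combined group. Another quantile normalization left 27.1% on it, against 17.3% for the next. A difference in signal distribution predicted a share at most 5 percentage points above the next, which was not seen. The share lay above a bound of 25% set beforehand, but with a jackknife error of 4.69 percentage points over the 9 arrays. A difference in signal distribution thus cannot be told apart from other sources at this number of arrays. A day shared by arrays of the same number stays open too: the correlations of deviations were 0.184, 0.211 and 0.226 between the replicates 3 and 0.247 between DMSO replicate 1 and combined replicate 1, but between -0.0739 and 0.039 for the other 5 same-number pairs. The highest correlation between arrays of different groups, 0.254, joined different numbers, thapsigargin replicate 2 and combined replicate 1. With the axis as a covariate 4296 genes were higher and 4291 lower after thapsigargin. The axis was taken from the residuals of the same fit. By construction it leaves the log2 changes as they are and takes up residual variance, so these counts do not test it. No biological explanation was tested.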

How the results depend on the processing

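The alternatives with the first within-group component, those that left out 2 or 3 arrays together and, for the lists, another quantile normalization were chosen after seeing the data. Counts are given in the order thapsigargin against DMSO, thapsigargin with forskolin against thapsigargin, and thapsigargin with forskolin against DMSO. Limma's treat, which by construction calls fewer genes, gave 1164, 94 and 1000 higher and 1077, 44 and 980 lower genes, with 56 moved the opposite way by forskolin and 19 moved further. Leaving out the farthest array of each group gave 527 higher and 361 lower genes for added forskolin, with 496 moved the opposite way and 198 further. The fit then had fewer arrays, and 790 of the 1745 genes were still called in the same direction. Leaving out single arrays gave between 568 and 1101 lower genes for added forskolin, between 675 and 1232 moved the opposite way and between 253 and 444 moved further. Leaving out DMSO replicate 1 and combined replicate 1 together gave 778 higher and 805 lower for added forskolin. Apart from these, counts stayed within 1.5 times of those reported under the alternatives run, and no named gene reversed. Over all alternatives 316 values of named genes lost and 14 gained their call, as did 79 and 34 list results, 34 of the losses with an estimated correlation and 27 of the gains with fry. The calcium list in thapsigargin with forskolin against DMSO did not pass camera (adjusted p = 0.811), where its direction was down. Its median log2 change was -0.07 and its mean 0.04. With fry, which does not compare the list with other genes, it passed upward (adjusted p = 0.0104). The cause was not tested further. With the replicate number as a block, 4085, 770 and 4039 genes were higher and 3933, 812 and 4001 lower, with 961 moved the opposite way and 348 further. The numbers were not taken to pair the samples, since only 4 of 9 same-number pairs of arrays deviated together with a correlation over 0.1. Best matches were sought among the 3 arrays of another group, and 10 of 18 had the same number. These matches do not speak against a pairing, which stays open. Leaving out probe sets by ID suffix was not run, since no ID has such a suffix. Signal over background is unknown in these values, so genes with low values may hide changes.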

Other observations

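The gene families here were chosen after the data were examined. Several families of protein synthesis and glycosylation rose with thapsigargin beyond the lists above, 1 of them with the preset correlation alone. Of 18 cytosolic aminoacyl-tRNA synthetase genes, whose enzymes load tRNAs, 17 rose and 0 fell, with Wars at 2.19 ± 0.05, Eprs at 1.79 ± 0.06 and Lars at 1.69 ± 0.06 (camera adjusted p = 4.08e-14, and adjusted p = 0.038 with an estimated correlation). Of 16 mitochondrial ones 7 rose and 0 fell, with Nars2 at 1.32 ± 0.09 (adjusted p = 0.000183, and adjusted p = 0.038 with an estimated correlation). Of 51 genes of translation initiation factors and their regulators 27 rose and 6 fell (adjusted p = 1.15e-06, and adjusted p = 0.038 with an estimated correlation), and of 71 mitochondrial ribosomal protein genes 39 rose and 8 fell (adjusted p = 6.32e-06, and adjusted p = 0.146 with an estimated correlation). Of 22 genes of the oligosaccharyltransferase and N-glycan precursor synthesis 17 rose and 1 fell, with Alg8 at 1.44 ± 0.05 and Dpagt1 at 1.22 ± 0.05 (adjusted p = 5.87e-09, and adjusted p = 0.00764 with an estimated correlation). Of 19 COPI and TMED genes of Golgi transport 12 rose and 4 fell, with Tmed9 at 0.94 ± 0.08 (adjusted p = 0.000653, and adjusted p = 0.038 with an estimated correlation).

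Of 14 guanylate-binding and immunity-related GTPase genes, which interferon induces, 12 fell and 1 rose with thapsigargin, with Iigp1 at -3.64 ± 0.11 and Gbp4 at -2.50 ± 0.24 (adjusted p = 2.96e-05, and adjusted p = 0.0652 with an estimated correlation). Of 35 protocadherin genes 12 fell and 2 rose, with Pcdhb22 at -1.75 ± 0.08 and Pcdh19 at 1.29 ± 0.07 (adjusted p = 0.00823, and adjusted p = 0.0412 with an estimated correlation). Among 32 chemokine genes 6 fell and 1 rose when forskolin was added (adjusted p = 0.00403, and adjusted p = 0.364 with an estimated correlation), while Il6 rose. The MHC genes, of which 11 of 34 fell and 2 rose with thapsigargin, passed with the preset correlation (adjusted p = 0.0414, and adjusted p = 0.251 with an estimated correlation), and the proteasome, tubulin, phosphodiesterase and vomeronasal receptor families did not (adjusted p from 0.406 to 0.802). The families above that passed kept their direction in these comparisons when the arrays were centred on their medians or quantile-normalized again. For added forskolin, camera with the preset correlation passed cytosolic tRNA synthetase (adjusted p = 0.00425), initiation factor (0.00339) and mitochondrial ribosomal protein genes (0.00247) downward. It passed COPI and TMED genes upward (0.0362). Few members changed singly: 2 of 18, 3 of 51 and 4 of 71 fell, and 1 initiation factor gene rose. Of the 19 COPI and TMED genes 1 rose. Median log2 changes were small, at -0.08, -0.07, -0.09 and 0.06 in the same order. None of these families passed with an estimated correlation (adjusted p = 0.416, 0.274, 0.364 and 0.257). Of 1088 olfactory receptor genes, whose transcripts belong to sensory neurons, 14 rose and 28 fell with thapsigargin (adjusted p = 0.802), where 35.0% of all genes were called.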
